A study of Mus musculus with 7 samples.

How the data were processed

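Acetylation and methylation marks of histone H3 were mapped in E14 cells, a mouse embryonic stem cell line of 129/Ola background, kept without feeder cells on gelatin in medium with serum and LIF. Chromatin was cut with micrococcal nuclease (MNase), at 600 or 1200 U for 15 or 45 min, before immunoprecipitation, so that the DNA recovered was mostly that of single nucleosomes. Per the labels' protocols, fragments of 145 to 175 b were taken from a gel and sequenced as 100 b paired-end reads. The labels list 2 samples each for H3K27Ac, H3K27me3 and H3K4me3 and 1 for H3K9me3, 7 in all, and do not say which digestion each sample had.

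The deposited data used here are 1 table per mark over a shared map of 10292808 nucleosomes, plus 1 small table of expected counts per mark. The submitters' processing notes name Bowtie, with no version, and the genome build mm9. The nucleosome caller, the rule for assigning a read to a nucleosome and the treatment of duplicate reads are not given in the sources used here. Per the file headers, the authors' tables give for every nucleosome a raw count, which is whole and not normalized. Per the file headers they also give the height of the nucleosome peak, a signal whose scale is not stated. The authors' expected counts, used here as a score with no stated model, are listed by MNase count class from 0 to 16, each with an upper count. The deposited tables have 1 count column per mark and none per replicate, and whether the replicates were pooled is not stated. The spread between replicates could therefore not be measured, no test between groups of samples was made, and all intervals cover counting error only.

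The 4 tables were joined row by row after a check that their positions, widths and heights were identical. The expected counts depend on an MNase count that no column used here gives for a nucleosome. The fallback fixed beforehand was used in their place, in which the expectation of a mark is its mean count over the nucleosomes of the same chromosome. A nucleosome was called marked when the upper-tail Poisson probability of its count passed a Benjamini-Hochberg threshold of 0.05 over all nucleosomes. Because counts vary far more than a Poisson variable, these calls mean a count above the chromosome's mean beyond counting error, and not necessarily enrichment over input chromatin. The number of nucleosomes called for 2 marks was divided by the number expected if the marks were independent, and set beside 100 seeded circular shifts of one mark's calls along each chromosome. Runs of adjacent called nucleosomes, the autocorrelation of counts over 1 to 50 nucleosomes, and counts over expectation in windows of 10 kb were computed per mark. Shares have 95% Wilson intervals, and folds have exact 95% Poisson intervals on the window's count.

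Regions were named by a rule fixed before the data were examined: for each mark, the 5 windows of 10 kb with the highest fold and the 3 longest runs of called nucleosomes. Coordinates are those of the files, in mm9. The gene table at hand is of assembly GRCm38.p6, another build, so no gene was assigned to a region, and the promoter profiles, promoter classes and gene lists that had been planned were not run. Further regions were chosen after their values were seen, and are named as such.

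On simulated Poisson counts at each mark's mean over the 241576 nucleosomes of chromosome 19, with 200 nucleosomes raised 4-fold, the calling step recovered 72.5% for H3K27Ac, 86.0% for H3K27me3, 73.5% for H3K4me3 and 12.5% for H3K9me3. For nucleosomes raised 8-fold it recovered 100% for each of H3K27Ac, H3K27me3 and H3K4me3, and 89.5% for H3K9me3. The shallow H3K9me3 table thus limits calls for single nucleosomes. False calls numbered at most 12 in these simulations. Real counts vary more than the simulated ones, so these numbers of false calls do not carry over to the data. The 200 raised nucleosomes are also a far smaller share than that called in the data for H3K27Ac, H3K27me3 and H3K4me3. The lowest count called therefore differs for these marks, and their recovery at 4-fold does not carry over either.

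Alternatives fixed beforehand were a threshold of 0.001, a background from the median of 1 Mb windows, a fold of at least 4, removal of the 563 nucleosomes in the top 0.1% of counts in all 4 tables, thinning to the smallest total, a local expectation over 200 nucleosomes, removal of nucleosomes at 0 in all 4 tables, windows of 5 and 50 kb, windows over 4-fold, co-occurrence on the same or the next nucleosome, and runs that bridge 1 nucleosome. Added after the data were seen were the authors' upper count of the top MNase class as a threshold, a binomial test, at each nucleosome, of a mark's count given the 4-mark total (Benjamini-Hochberg threshold of 0.05, for counting error only), strata of equal counts of the other 2 marks, runs of nucleosomes with a count of 0, singly and merged where at most 200 nucleosomes apart, and windows of 1 Mb in which H3K9me3 was compared at matched counts of the other marks. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9.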

Results

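Nucleosome-resolution maps of 4 histone H3 modifications were examined in E14 mouse embryonic stem cells. H3K4me3 is a mark of promoters, H3K27Ac of active promoters and enhancers, H3K27me3 of Polycomb repression and H3K9me3 of constitutive heterochromatin. The map held 10292808 nucleosomes on 21 chromosomes, with a median spacing between centres of 220 bp. Counts summed to 39686276 for H3K27Ac, 52828288 for H3K27me3, 42722533 for H3K4me3 and 19194922 for H3K9me3. The mean per nucleosome was 3.86, 5.13, 4.15 and 1.86 in that order. Variance exceeded the mean 9.59-fold for H3K27Ac, 8.93-fold for H3K27me3 and 6.57-fold for H3K4me3, but 1.60-fold for H3K9me3. A count of 0 was found at 51.2% of nucleosomes for H3K27Ac, 41.6% for H3K27me3, 19.6% for H3K4me3 and 21.8% for H3K9me3. There is 1 count column per mark, so replicate error is unknown for every value below, and intervals cover counting error only.

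The first comparison asked how many nucleosomes carried each mark above the mean of their chromosome. H3K27me3 was called at 1742918 nucleosomes, or 16.9% of the map (95% Wilson interval 16.91 to 16.96%). H3K27Ac was called at 1556044 (15.1%, 15.10 to 15.14%) and H3K4me3 at 1222650 (11.9%, 11.86 to 11.90%). H3K9me3 was called at 2640, or 0.0256% (0.0247 to 0.0266%). Called nucleosomes held 60.7% of all H3K27Ac counts, 55.8% of H3K27me3 counts, 44.4% of H3K4me3 counts and 0.301% of H3K9me3 counts. On autosomes the lowest count called was 9 to 13 for H3K27Ac, 10 to 15 for H3K27me3, 10 to 13 for H3K4me3 and 11 to 12 for H3K9me3. The numbers depend strongly on the threshold: a required fold of 4 left 607682 for H3K27Ac, 308713 for H3K27me3 and 352956 for H3K4me3. H3K9me3 calls fell to 875 at a threshold of 0.001 and 550 with a local expectation. The authors' upper counts for the top MNase class, a threshold added after the data were seen, are 7 for H3K9me3 and 27 for H3K27me3. Above these lay 43835 nucleosomes for H3K9me3 and 48850 for H3K27me3, so the size of the gap between these marks depends on the calling rule.

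The second comparison asked which marks were called on the same nucleosome. H3K27Ac and H3K4me3 shared 947150 nucleosomes, 5.12 times the number expected from independence, and 77.5% of H3K4me3 nucleosomes were called for H3K27Ac. H3K27Ac and H3K27me3, which modify the same lysine, shared 1111068, a ratio of 4.22, and H3K27me3 and H3K4me3 shared 902354, a ratio of 4.36. H3K9me3 calls overlapped those of H3K4me3 at 1308 nucleosomes (ratio 4.17), of H3K27me3 at 1565 (3.50) and of H3K27Ac at 1266 (3.17). Each of the 6 ratios lay above the highest of its 100 circular shifts, which was 1.45 or lower. Their size depends on the setting: over alternatives fixed beforehand H3K27Ac with H3K27me3 ranged from 2.44, when the same or the next nucleosome counted, to 9.98 with a fold of at least 4. Above the authors' upper counts the ratios were 43.7 for H3K27Ac with H3K27me3, 47.6 for H3K27Ac with H3K4me3 and 40.5 for H3K27me3 with H3K4me3. Rarer calls allow a higher ratio, so larger values in stricter settings do not mean that a larger share of nucleosomes carried both calls. A setting added after the data were seen compared nucleosomes only within strata of equal counts of the other 2 marks. The ratios fell to 1.199 for H3K27Ac with H3K27me3, 1.37 for H3K27Ac with H3K4me3 and 1.13 for H3K27me3 with H3K4me3. Each lay above 20 permutations of one mark's calls within strata, which reached 1.001 at most. Where calls are frequent in a stratum the ratio cannot rise far above 1. The fall therefore does not measure how much of the sharing remained. In the same strata H3K9me3 gave 1.07 with H3K4me3, 1.19 with H3K27me3 and 0.898 with H3K27Ac, the last in the opposite direction.

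**Figure D1:**
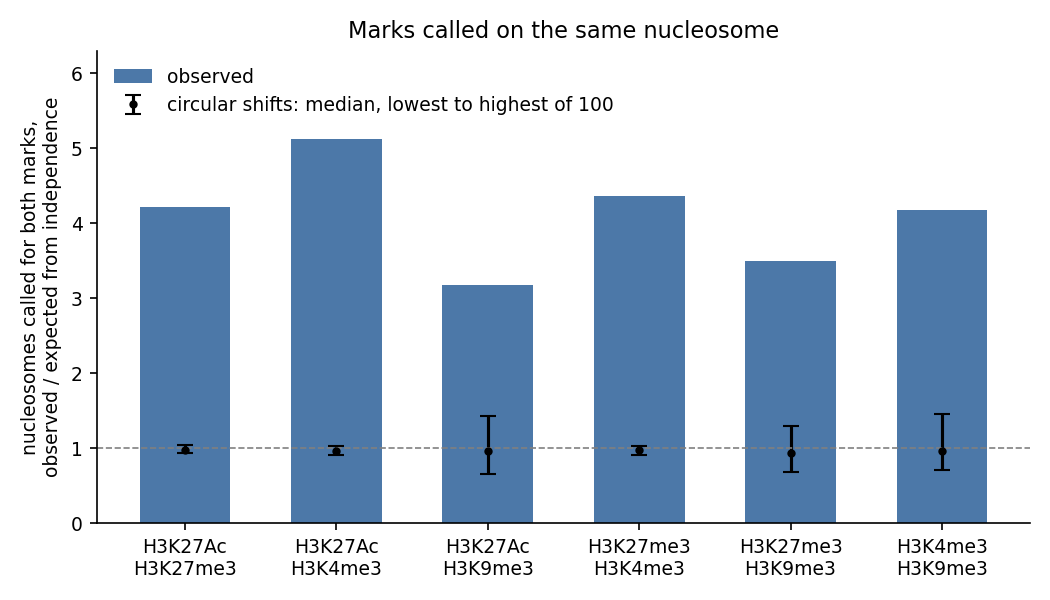
Bars give the number of nucleosomes called for both marks of a pair, divided by the number expected from independence. Points and whiskers give the median and the lowest to highest of 100 circular shifts; the bars run from 3.17 to 5.12 and the whiskers reach 1.45 at most.

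Among combinations, all of H3K27Ac, H3K27me3 and H3K4me3 without H3K9me3 were called at 753559 nucleosomes (7.32%), 24.1 times the number expected from independence. H3K4me3 alone was called at 127610 nucleosomes, 0.148 times expectation, H3K27Ac alone at 252396 (0.222 times) and H3K27me3 alone at 483860 (0.371 times). H3K27me3 with H3K4me3 but not H3K27Ac or H3K9me3 was called at 147642 nucleosomes, 0.840 times the number expected if all 4 marks were independent. That value is not a depletion of the pair, whose calls overlapped at 4.36 times expectation when the other marks were disregarded. The marks were precipitated in separate samples, so calls for both do not show a bivalent nucleosome. All 4 marks were called at 1042 nucleosomes against 8.03 expected. That count was 585 without the nucleosomes in the top 0.1% of all 4 tables and 470 at a threshold of 0.001. H3K27Ac, H3K27me3 and H3K4me3, with or without H3K9me3, were called together at 754601 nucleosomes, but at 246933 at 0.001, 124578 after thinning to equal totals and 97734 with a fold of 4. Ratios to expectation for combinations were computed for the main setting only. Median spacing to the next nucleosome was 215 bp where none of H3K27Ac, H3K27me3 and H3K4me3 was called and 255 bp where all 3 were. Mean peak width differed as well, at 106.8 bp where none of the 4 marks was called and 159.6 bp where those 3 were called without H3K9me3. Counts were not scaled to width, and whether width accounts for the spacing or for the shared calls was not tested.

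A test against the nucleosome's own 4-mark total was added after the data were seen. In it 37 nucleosomes passed the threshold for more H3K27me3 than its share of all counts predicts. H3K4me3 had 239 such nucleosomes, of which 55.6% lay on chromosome Y, and H3K27Ac had 298. H3K9me3 had 429001, with a mean of 4.58 H3K9me3 counts beside 0.133 for H3K27Ac, 0.404 for H3K27me3 and 0.888 for H3K4me3. These nucleosomes had few counts of the other marks and more H3K9me3 than the table's mean of 1.86. Of them 0.285% were called marked for H3K9me3, a call that needed a count of 11 to 12 on autosomes and misses most 4-fold nucleosomes at this depth. H3K9me3 holds 12.4% of all counts and H3K27me3 34.2%, and fewer counts suffice to pass where the share is smaller. The numbers passing are therefore not comparable between marks.

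The spread of each mark along neighbouring nucleosomes was measured next. Single calls with no called neighbour made up 40.8% of H3K27Ac, 41.4% of H3K27me3, 47.1% of H3K4me3 and 70.2% of H3K9me3 calls. After shuffling of calls the shares were 72.0, 69.0, 77.7 and 99.9%. The order of the marks depends on the threshold: at 0.001 the shares were 54.1, 59.4, 62.7 and 42.2%, lowest for H3K9me3. With a fold of 4 those of H3K27me3 (74.5%) and H3K4me3 (70.96%) passed that of H3K9me3. Counts of adjacent nucleosomes correlated at r = 0.46 for H3K27Ac, 0.45 for H3K27me3, 0.43 for H3K4me3 and 0.24 for H3K9me3. At 50 nucleosomes the values were 0.28 for each of H3K27Ac, H3K27me3 and H3K4me3 and 0.098 for H3K9me3. These are correlations across nucleosomes, which are not independent replicates.

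The longest H3K27Ac run was 53 nucleosomes at chromosome 10, 80127381 to 80138411, with mean counts 4.79, 3.25 and 3.98 times the chromosome's for H3K27Ac, H3K27me3 and H3K4me3. The next were 42 nucleosomes at chromosome 10, 77635771 to 77644931, and 41 at chromosome 4, 107283421 to 107292861. For H3K27me3 the 3 longest runs each held 44 nucleosomes, at chromosome 8, 96473221 to 96482471, chromosome 17, 27501421 to 27511541, and chromosome 17, 31041911 to 31052151. In these 3 runs H3K27Ac was 4.25, 5.78 and 6.64 times its chromosome mean and H3K27me3 3.34, 5.01 and 5.51 times. The longest H3K4me3 runs were 83 and 72 nucleosomes at chromosome 11, 3059541 to 3080111 and 3080701 to 3098541, and 40 at chromosome Y, 2851191 to 2861291. The chromosome 11 runs were high in every mark, with 67.5 and 72.2% of their nucleosomes in the top 0.1% of all 4 tables. The chromosome Y run had 34.3-fold H3K4me3, 26.7-fold H3K27Ac and 0.840-fold H3K9me3. The 3 longest H3K9me3 runs, of 72, 62 and 28 nucleosomes, also lay between 3041241 and 3098541 on chromosome 11.

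Runs of nucleosomes with a count of 0, examined after the data were seen, set H3K9me3 apart. H3K9me3 had 32 runs of at least 50 nucleosomes without a single count, 6838 nucleosomes on 13 chromosomes, while H3K4me3 had none. H3K27Ac had 83 such runs and H3K27me3 had 13, the longest being 136 and 75 nucleosomes. The longest H3K9me3 run held 748 nucleosomes at chromosome 8, 127514031 to 127690261. From the 200 nucleosomes on each side, 1773 H3K9me3 counts would have been expected there. Over the same stretch the tables held 4028 H3K27me3 counts (0.433 times the flanking mean per nucleosome), 5107 H3K27Ac counts (0.644 times) and 6923 H3K4me3 counts (0.912 times). Others were 653 nucleosomes at chromosome 7, 5605211 to 5780861, and 584 at chromosome 17, 7962631 to 8099431. In the chromosome 17 run H3K27me3 was 0.917, H3K27Ac 1.252 and H3K4me3 1.34 times flanks that hold further runs of 0. Over the 32 runs the median ratio to the flanks was 0.469 for H3K27me3, 0.749 for H3K27Ac and 0.968 for H3K4me3. Medians of 1000 sets of random runs of the same lengths spanned 0.858 to 1.15, 0.789 to 1.23 and 0.872 to 1.12. Several runs were pieces of one stretch, and runs at most 200 nucleosomes apart merged into 24 stretches. Against flanks free of such runs the medians were 0.446 for H3K27me3, 0.728 for H3K27Ac and 0.973 for H3K4me3. H3K27me3 was below its flanks in 24 stretches, H3K27Ac in 21 and H3K4me3 in 13. The merged chromosome 17 stretch, 7941961 to 8163961, had 0.605 for H3K27me3, 1.104 for H3K27Ac and 1.65 for H3K4me3.

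**Figure D2:**
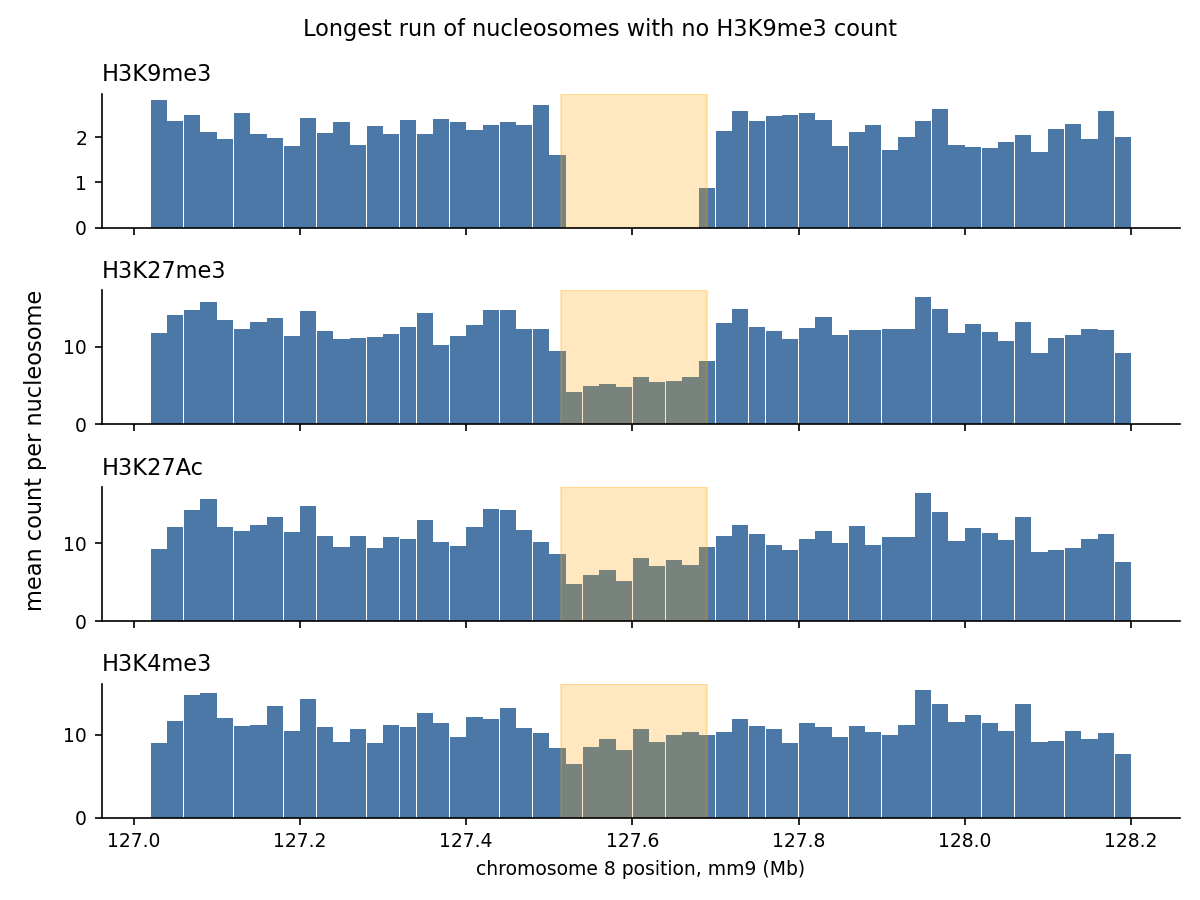
Mean count per nucleosome in bins of 20 kb along chromosome 8 (mm9) is plotted for each mark, with the run of 748 nucleosomes shaded. Within the shaded stretch H3K9me3 was 0 and H3K27me3, H3K27Ac and H3K4me3 were 0.433, 0.644 and 0.912 times their flanks.

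At domain scale, 12.6% of 253872 windows of 10 kb exceeded 2-fold for H3K27Ac (12.5 to 12.7%), 9.68% for H3K27me3 (9.56 to 9.79%), 8.58% for H3K4me3 (8.47 to 8.69%) and 0.151% for H3K9me3 (0.137 to 0.167%). Over 4-fold the shares were 0.344, 0.0484, 0.0473 and 0.0130%, and H3K9me3 exceeded 2-fold in 0.268% of windows of 5 kb. Spearman's rho across windows was 0.98 between H3K27Ac and H3K27me3, 0.97 between H3K27Ac and H3K4me3 and 0.96 between H3K27me3 and H3K4me3. H3K9me3 correlated with H3K27Ac, H3K27me3 and H3K4me3 at 0.61, 0.66 and 0.63. Windows are not independent replicates; 100 circular shifts gave rho between -0.10 and 0.030. The log2 ratio of H3K27Ac to H3K27me3 varied across windows with an SD of 0.32, against 0.20 from counting error. For H3K27Ac to H3K4me3 the SD was 0.44 against 0.20, and for H3K27me3 to H3K4me3 it was 0.38 against 0.19. Part of this followed the total of the 2 marks: after windows were matched on it the SDs were 0.26 for H3K27Ac to H3K27me3, 0.28 for H3K27Ac to H3K4me3 and 0.30 for H3K27me3 to H3K4me3.

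**Figure D3:**
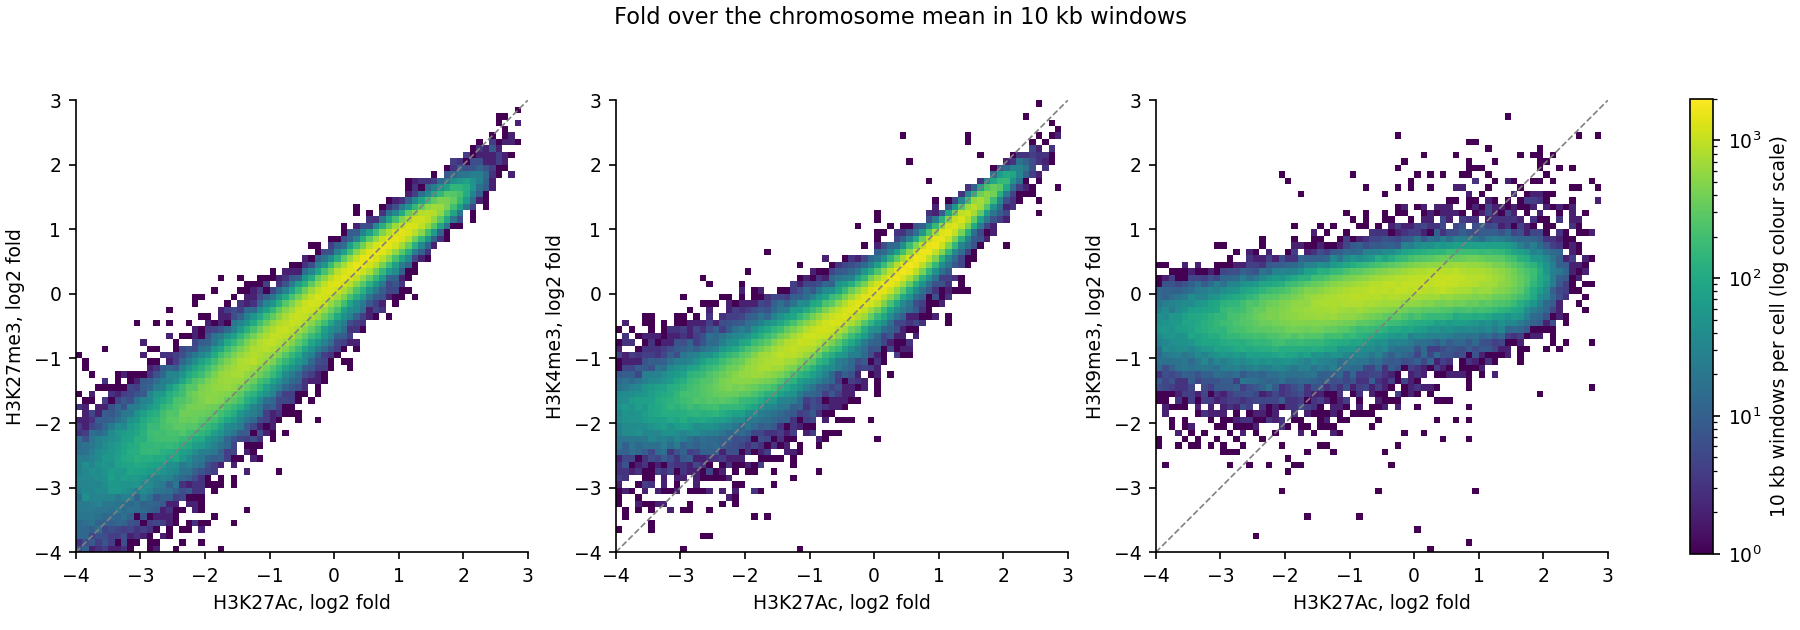
Each panel sets the log2 fold over the chromosome mean of one mark against that of H3K27Ac in windows of 10 kb with at least 20 nucleosomes, with the number of windows as colour on a log scale and the diagonal dashed; windows outside the plotted range are not drawn. H3K27me3 and H3K4me3 follow H3K27Ac (rho 0.98 and 0.97) more closely than H3K9me3 does (0.61).

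The window with the highest fold was the same for all 4 marks, at chromosome 17, 39980001 to 39990000. It reached 85.6-fold for H3K9me3 (95% Poisson interval 83.6 to 87.6), 78.9-fold for H3K27Ac (77.7 to 80.2), 54.3-fold for H3K27me3 (53.4 to 55.2) and 32.6-fold for H3K4me3 (31.8 to 33.4). Without the 563 nucleosomes in the top 0.1% of all 4 tables it was no longer among the 5 highest of any mark, though that removal lowers such windows by construction. Windows between 3040001 and 3100000 on chromosome 11 were also high in every mark with all nucleosomes kept, such as 3060001 to 3070000 with 36.3-fold H3K9me3 and 29.4-fold H3K27me3. The removal left 11 of the 39 nucleosomes of that window, with 27.4-fold H3K9me3, 7.35-fold H3K4me3, 2.67-fold H3K27me3 and 0.938-fold H3K27Ac. Those left fell short of the top 0.1% in at least 1 mark. The difference between marks can follow from this selection and does not show enrichment of H3K9me3 alone. On chromosome X, 166430001 to 166440000 had 38.5-fold H3K27Ac, 30.3-fold H3K27me3 and 9.54-fold H3K9me3. These became 17.4, 14.5 and 5.28 without the nucleosomes in the top 0.1% of all 4 tables. The neighbouring window, 166420001 to 166430000, had 35.1-fold H3K27Ac with all nucleosomes kept. On chromosome Y, 2850001 to 2860000 had 31.8-fold H3K4me3 (30.8 to 32.8) and 26.8-fold H3K27Ac, with 0.803-fold H3K9me3 (0.529 to 1.17). The windows 2880001 to 2890000 and 2890001 to 2900000 of chromosome Y had 26.0-fold and 24.6-fold H3K4me3.

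Windows with the highest share of a mark in the 4-mark total were chosen after their values were seen. They were taken among windows with at least 20 nucleosomes and 100 counts. For H3K4me3 the first was chromosome Y, 2780001 to 2790000, with 16.8-fold H3K4me3 (16.1 to 17.6) against 6.50-fold H3K27me3 (5.97 to 7.07). For H3K9me3 it was chromosome 6, 130490001 to 130500000, with 72 H3K9me3 counts (0.989-fold) beside 41 of H3K4me3, 3 of H3K27me3 and 2 of H3K27Ac. For H3K27me3 it was chromosome X, 21960001 to 21970000, with 1.68-fold H3K27me3 (1.28 to 2.17) and 0.802-fold H3K27Ac (0.483 to 1.252). These 2 folds rest on 59 and 19 counts. The intervals do not cover the choice of the most extreme of many windows, so a parting of the marks at this window is not shown.

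Chromosomes differed in count density. Chromosome X had 0.256 times the autosomal mean count for H3K27Ac (0.255 to 0.256), 0.284 for H3K27me3 (0.284 to 0.285), 0.307 for H3K4me3 (0.307 to 0.308) and 0.460 for H3K9me3 (0.459 to 0.461). These ratios are not corrected for the number of X copies per cell, which was not measured here. Chromosome 11 was highest among autosomes for H3K27Ac (1.34), H3K27me3 (1.28) and H3K4me3 (1.27), and chromosome 3 was lowest (0.698, 0.749 and 0.753). For H3K9me3 chromosome 8 was highest, at 1.19, and the other autosomes lay between 0.933 and 1.09. The share of nucleosomes called for H3K27me3 was 19.9% on chromosome 8 and 9.88% on X (3.35% at a threshold of 0.001), where the lower mean brings the lowest called count down to 6.

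In windows of 1 Mb, examined after the data were seen, the H3K9me3 excess lay in 1 segment of chromosome 8. From 54000001 to 111000000, all 55 windows with at least 2000 nucleosomes had over 1.2 times the H3K9me3 count found elsewhere at matched counts of the other 3 marks, with a median of 1.39 (range 1.22 to 1.63); 2 Mb of the segment gave no value. The threshold of 1.2 defined the segment. Without matching, the median window of the segment had 1.51 times the autosomal median for H3K9me3, 1.37 for H3K27me3, 1.31 for H3K27Ac and 1.27 for H3K4me3. The other 69 windows of the chromosome had a median of 0.989. Outside chromosome 8, 5 of 2239 autosomal windows exceeded 1.2, and the highest median of any of 1267 stretches of the same length was 1.04.

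**Figure D4:**
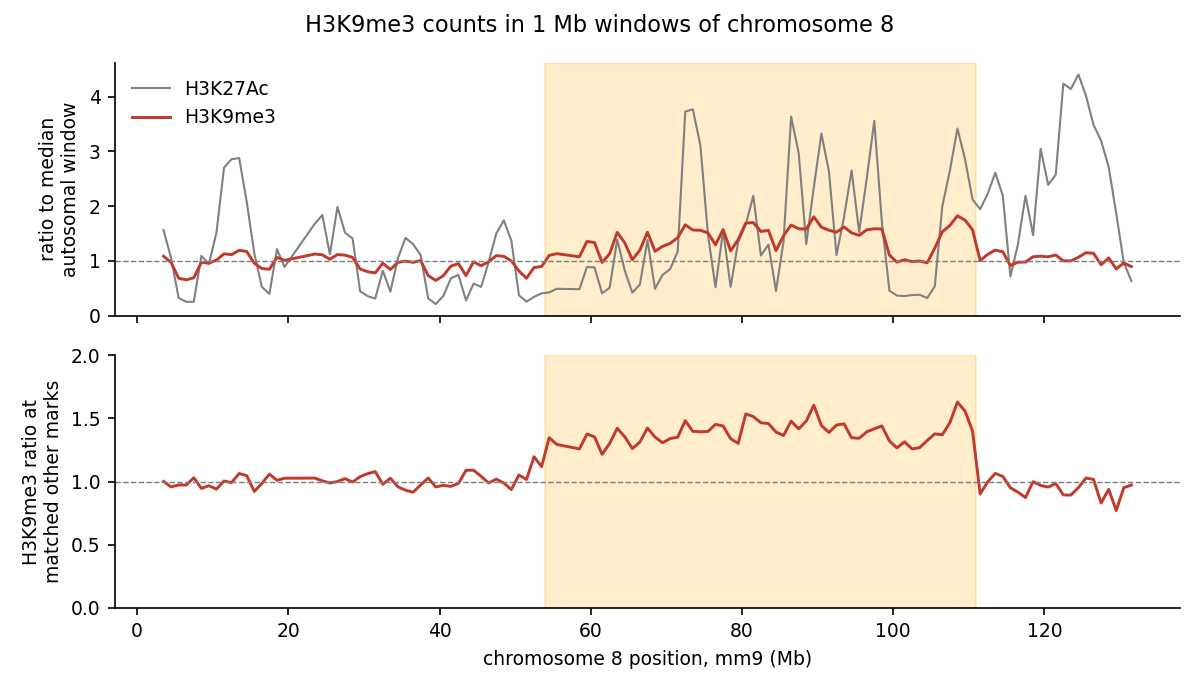
The upper panel plots counts per nucleosome in windows of 1 Mb along chromosome 8 (mm9) as a ratio to the median autosomal window, for H3K9me3 and H3K27Ac; the lower panel plots H3K9me3 as a ratio to that of autosomal windows with matched counts of the other 3 marks. The shaded segment, 54000001 to 111000000, has a median matched ratio of 1.39, against 0.989 over the rest of the chromosome.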

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

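The settings with the authors' upper count, the share of the 4-mark total and the strata were added after the data were seen. No paired analysis was possible because the tables carry no replicate columns; for the same reason no replicate could be left out. The alternatives intended for promoters and gene lists were not run, as no annotation of build mm9 was used. The 6 window correlations kept their direction and lay above all their circular shifts in windows of 5 and 50 kb, without the shared top and without nucleosomes at 0, the settings run for them. The 6 co-occurrence ratios did so under every alternative chosen beforehand for them, but their sizes moved. They ranged from 2.44 to 9.98 for H3K27Ac with H3K27me3, 2.98 to 10.9 for H3K27Ac with H3K4me3, 2.69 to 11.6 for H3K27me3 with H3K4me3, 2.27 to 7.08 for H3K27Ac with H3K9me3, 2.54 to 13.6 for H3K27me3 with H3K9me3 and 2.75 to 11.9 for H3K4me3 with H3K9me3. Each lowest value came from counting the same or next nucleosome, and the highest from a fold of 4 or a threshold of 0.001. Above the authors' upper counts they were 43.7, 47.6, 40.5, 7.98, 14.2 and 7.46 in that order. Settings with fewer calls allow higher ratios, so the sizes are not comparable across settings. Within strata of the other 2 marks H3K27Ac with H3K9me3 reversed to 0.898; the cause was not tested. H3K9me3 results rest on the smallest total, at which 4-fold nucleosomes are mostly missed.

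Values are given for H3K27Ac, H3K27me3, H3K4me3 and H3K9me3 in that order unless named, and the causes of the shifts were not tested beyond the stricter or shallower setting itself. Marked nucleosomes numbered 834288, 815606, 566973 and 875 at a threshold of 0.001, and 777577, 802699, 560115 and 550 with a local expectation. A fold of 4 gave 607682, 308713 and 352956 for H3K27Ac, H3K27me3 and H3K4me3, and thinning 837211, 589746 and 522253. The authors' upper count gave 64540, 48850, 61240 and 43835, and the share of the 4-mark total 298, 37, 239 and 429001. H3K27Ac, H3K27me3 and H3K4me3 were called together at 246933 nucleosomes at 0.001, 97734 with a fold of 4 and 124578 after thinning. All 4 marks were called at 470 at 0.001 and 585 without the shared top. Calls standing alone made up 54.1, 59.4, 62.7 and 42.2% at 0.001, and 26.97, 26.5, 32.2 and 65.8% with bridging. For H3K27Ac, H3K27me3 and H3K4me3 they were 60.7, 74.5 and 70.96% with a fold of 4 and 57.8, 71.3 and 68.5% after thinning, and H3K9me3 had 81.9% without the shared top. Autocorrelation at 1 nucleosome was 0.41, 0.38 and 0.36 for H3K27Ac, H3K27me3 and H3K4me3 after thinning, and 0.44, 0.44 and 0.16 for H3K27Ac, H3K27me3 and H3K9me3 without the shared top. The X ratio was 0.292, 0.325, 0.351 and 0.525 without nucleosomes at 0 in all tables. The share marked on X was 2.83, 3.35, 1.38 and 0.0143% at 0.001, 7.09, 8.57 and 5.81% for H3K27Ac, H3K27me3 and H3K4me3 without nucleosomes at 0, 7.11% for H3K27me3 with a fold of 4, and 0.0163% for H3K9me3 without the shared top. Windows over 2-fold made up 13.4, 10.7, 9.38 and 0.268% at 5 kb, 11.6, 8.13, 7.56 and 0.108% at 50 kb, and 11.1, 7.80, 7.16 and 0.125% without nucleosomes at 0. Windows over 4-fold made up 0.344, 0.0484, 0.0473 and 0.0130%.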

Other observations

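Of the tests below, only the shuffling of H3K9me3 counts was set out before its result was seen; all the others were chosen after the pattern, or values bearing on it, had been seen. The design names only the marks, so no biological explanation by a group of samples was tested; the tests on absent DNA, extra copies and a mixture of cells concern the genomes of the cells behind the tables.

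The authors' deposited table of expected counts rises with the MNase count for every mark. Between MNase counts of 0 and 16 the authors' deposited table goes from 1.59 to 9.81 for H3K27Ac, from 2.08 to 12.6 for H3K27me3, from 1.91 to 9.63 for H3K4me3 and from 1.15 to 3.23 for H3K9me3. The upper count in the authors' deposited table at an MNase count of 16 is 25, 27, 23 and 7, against 15, 19, 15 and 6 for the 95th percentile of a Poisson variable of that mean. Nucleosomes above those upper counts numbered 64540, 48850, 61240 and 43835. The height of a nucleosome's peak, for which the reads used are not stated, correlated with its count at Spearman's rho 0.87, 0.89, 0.83 and 0.42 in the same order, across a seeded draw of 1000000 nucleosomes.

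The first pattern joins H3K27Ac, H3K27me3 and H3K4me3, marks of opposed chromatin states. They ranked windows nearly alike and shared called nucleosomes more often than independence predicts. Of nucleosomes called for any of the 3, 32.6% were called for all 3 and 37.3% for 1 only. Sequence counted in every table as multi-copy is argued against, as a whole cause, because extra copies raise every table and nucleosomes called for H3K27Ac and H3K27me3 had 4.12-fold H3K27Ac and 3.42-fold H3K27me3 but 1.38-fold H3K9me3 (1.304 to 1.48 over the autosomes). After thinning to equal totals the co-occurrence ratio of H3K27Ac with H3K27me3 was 5.69, above all its circular shifts. Sharing beyond independence was thus present without unequal depth. The size of the ratio does not show that the extent of sharing held, because thinning leaves fewer calls and so allows a higher ratio. Nucleosomes called for all 3 marks fell from 754601 to 124578 after thinning. How far depth affects the extent of sharing is therefore undecided. A candidate explanation that stays open is that the libraries recovered the same accessible or well-positioned nucleosomes. The authors' deposited table has an expected H3K27me3 count that rises 6.06-fold with the MNase count, and an expected H3K9me3 count that rises 2.82-fold. The 1.38-fold H3K9me3 argues against recovery that raised every table alike, but not against recovery that raised H3K9me3 less. Extra copies could raise an MNase count too, so the rise alone does not single out recovery. A real sharing of nucleosomes by the marks, or by alleles and cells of different state, also stays open, because no MNase count per nucleosome was used here to remove the shared part.

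The second pattern is the 32 runs of nucleosomes with no H3K9me3 count. Low depth along whole chromosomes is argued against, as the longest run of 0 in 20 shuffles within chromosomes was 20 nucleosomes, against 748 observed. Shuffling removes local differences in recovery, so it cannot speak to low recovery at the runs themselves. From the flanking nucleosomes 9298 H3K9me3 counts were expected over the 32 runs, from 14.0 to 1773 per run. A filter on the H3K9me3 table alone is argued against, since H3K27me3 was also lowered, with a median ratio to the flanks of 0.446 over the 24 merged stretches that lay below all 1000 random sets. A candidate explanation is that this DNA was absent from the cells of the H3K9me3 library and from part of the cells behind the H3K27me3 and H3K27Ac tables, since the ratio to the flanks was lower for H3K27me3 than for H3K27Ac, and lower for H3K27Ac than for H3K4me3, in 87.5% of the merged stretches. That would mean that the 4 tables come from cells with different genomes, a hypothesis that reads of the single samples could test.

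The third pattern is the raised H3K9me3 count over chromosome 8, 54000001 to 111000000. The 36 windows of the chromosome over 1.3 without matching had a median of 1.42 at matched counts (SD of other autosomal windows 0.074). They lie in the segment that a matched ratio over 1.2 defined, so this median could not have been low and decides nothing. Dependence of H3K9me3 counts on recovery shared with the other marks is argued against by the comparison of stretches. At matched counts the segment, chosen on that ratio, had a median of 1.39, and the highest of 1267 stretches of the same length elsewhere had 1.04. Extra copies of the segment in the cells of the H3K9me3 library would raise all nucleosomes alike. In 4 classes of nucleosomes, from the lowest to the highest counts of the other marks, the ratio was 1.36 (1.356 to 1.373), 1.39, 1.46 and 1.45 (1.442 to 1.453). The highest and lowest classes differed by 0.083, which is small but beyond counting error, and no bound was set before the data were seen. Extra copies thus stay open but were not shown. A broad H3K9me3 domain was not tested and stays open, as do extra copies behind the other tables, whose unmatched counts were raised there too. The idea that the same mixture of cells made both this segment and the runs of 0 met a loose bound, with the log2 ratio of H3K27me3 to H3K4me3 at percentile 96.9 of same-length stretches, but failed on size. The runs predict an excess of 0.25 at matched H3K4me3 and the segment showed 0.048 (SD of stretches 0.066), while H3K27Ac went the other way, at -0.075 against a predicted 0.12. Without matching, the segment had 1.37 for H3K27me3, 1.31 for H3K27Ac and 1.27 for H3K4me3, the order that the mixture predicts. Size was compared at matched H3K4me3 counts only. The unmatched order says nothing on size, so it does not undo that failure.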
